A study of Mus musculus with 2 samples.

How the data were processed

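Total RNA of satellite cells from the tibialis anterior muscle was sequenced as 1 library of Cipc flox/flox and 1 of Cipc scko mice. Libraries were made with a VAHTS Universal V6 kit and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name CASAVA, HISAT2 2.0.4, StringTie 1.3.0 and the build GRCm38, without saying what each was used for. The annotation release, the counting tool and any filter are not given in the sources used here, nor is whether counting used strand. The authors deposited whole-number counts per Ensembl gene for both libraries, and FPKM values in a file per library, per the file headers. No gene in the deposited count table was at 0 in both libraries, and the smallest total was 2. The deposited FPKM are the counts rescaled: over 13719 genes counted in both libraries, the ratio of FPKM between libraries divided by the ratio of CPM lay between 0.9996 and 1.0002. They are therefore not an independent measurement and served as an alternative only.

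Symbols, positions and transcripts came from GENCODE vM21 on GRCm38, in which 16116 of 16190 gene identifiers had a symbol and 74 did not. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 and expressed as CPM. Genes entered with a CPM of at least 1 in a library and at least 20 counts over both, which left 12874. Log2 ratios of Cipc scko over Cipc flox/flox used a prior count of 0.5 per library, scaled to library size. A 95% interval of each ratio was the exact binomial (Clopper-Pearson) interval of the split of a gene's counts between the libraries. It covers counting error only, since reads without molecular identifiers are not independent molecules and variation between animals was not measured. A gene was called higher or lower when the ratio was at least 2-fold and the interval excluded equality. No p-value was computed, because 1 library per group leaves no residual degrees of freedom. A gene at 0 in a library was given a lower bound against a floor of 3 counts in that library, or 0.187 CPM in Cipc scko and 0.177 CPM in Cipc flox/flox.

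40 gene lists were fixed before the data were examined. A list with at least 5 members past the filter got its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched in 20 bins of mean expression. It was said to stand apart below percentile 2.5 or above 97.5. Genes were named by a rule fixed at the same time: Cipc, the 12 highest and 12 lowest genes by the interval limit nearest to equality (without predicted genes, pseudogenes, Xist and Y-linked genes), the 2 highest and 2 lowest members of each list with a CPM of at least 5, and 12 myogenic, cell cycle and clock genes. Rps2-ps10, the H2 class II genes, Ciita, H2-K1, H2-D1, H19, Myh1, Myh2, Myh3, Myh4, Myh8 and Rps18 fell outside the rule and were chosen after their values were seen.

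Near-identical copies were found with BLAST+ 2.17.0 among the longest transcripts of the genes in the table, at 95% identity over 80% of the shorter one. This marked 640 genes, 475 of them past the filter, whose separate values are uncertain. Chromosome medians used 9976 autosomal genes without such copies and with a mean CPM of at least 5. They were compared with 1000 random gene sets.

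The rule was tested on simulated data made from the mean profile and depths of these libraries, with 200 of 16190 genes changed. In the libraries themselves 37.2% of genes past the filter were called, so the simulated rates need not hold for them. With counting error alone it called 27 of 12380 unchanged genes and recovered 48.0% of 2-fold, 100% of 3-fold and 100% of 4-fold changes. With an assumed coefficient of variation between animals of 0.2 it called 372 of 12407 unchanged genes, and with 0.4 it called 3012 of 12498. Of 40 lists of unchanged genes drawn at random, 3 stood apart with counting error alone.

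Alternatives fixed beforehand were scaling by totals, DESeq2 1.42.0 size factors or the upper quartile, no filter or a CPM of 5, a prior count of 5, FPKM with a pseudocount of 0.1 or 1, totals without mitochondrial and the 10 most counted genes, other fold limits, wider intervals, and other summaries of lists. Leaving out a replicate was not possible.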

Results

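RNA was sequenced from cells labelled as satellite cells, the muscle stem cells that lie beneath the basal lamina of myofibres, isolated from the tibialis anterior muscle of mice. 1 library came from mice with floxed Cipc alleles (Cipc flox/flox, the control) and 1 from mice in which Cipc was deleted in satellite cells (Cipc scko). These are the genotype labels, while the sample titles read Cipc+/+ and Cipc-/-. Cipc encodes CLOCK-interacting pacemaker, a protein known as a repressor of the circadian transcription factor pair CLOCK and BMAL1. The labels name C57BL/6 as the strain of both. The count table held 16190 genes, with a total of 16830168 counts in the Cipc scko library and 16145870 in the Cipc flox/flox library. With 1 library per group no difference below has a replicate check: the values describe these 2 libraries, not the genotypes, and every interval covers counting error only.

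The first question was whether the targeted gene differed as the labels say. Cipc (ENSMUSG00000034157, GRCm38 chromosome 12, 86947043 to 86965362) had 594 counts in Cipc scko and 1907 in Cipc flox/flox, or 37.0 and 113 CPM (counts scaled to library size). The log2 ratio of Cipc scko over Cipc flox/flox was -1.61 (95% counting interval -1.74 to -1.47), a 3.05-fold lower level (2.78 to 3.34). Of the 12874 genes past the filter, 1117 (8.68%) had a ratio as low or lower. The count covers the whole gene and does not show which exons were read.

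Sex-linked genes and whole chromosomes also differed between the libraries. Xist, the RNA of the inactive X chromosome, had 4 counts in Cipc scko and 3898 in Cipc flox/flox, whereas the Y-linked genes Ddx3y, Uty and Kdm5d had 511, 155 and 348 counts in Cipc scko and 0 in Cipc flox/flox. Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4, had 688 and 576 counts in Cipc scko and 0 in Cipc flox/flox, at least 242-fold and at least 202-fold higher. The difference in sex-linked genes runs with genotype and cannot be separated from it in any comparison of these libraries. The 441 genes of chromosome 15 had a median log2 ratio 0.64 below that of all 9976 autosomal genes compared (deviation -0.64, against -0.14 to 0.22 in 1000 random gene sets of that size), and each of 4 equal groups of its genes, in order of position, lay below (-0.70, -0.49, -0.67 and -0.87). Chromosome 10 deviated by -0.35, and chromosomes 7, 4 and 9 by 0.40, 0.24 and 0.24. These 5 of 19 autosomes lay over 0.2 away and outside their random ranges. Chromosomes 3, 8, 11 and 16 also lay outside their random ranges, at smaller deviations of -0.13, 0.17, -0.12 and 0.18.

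**Figure D1:**
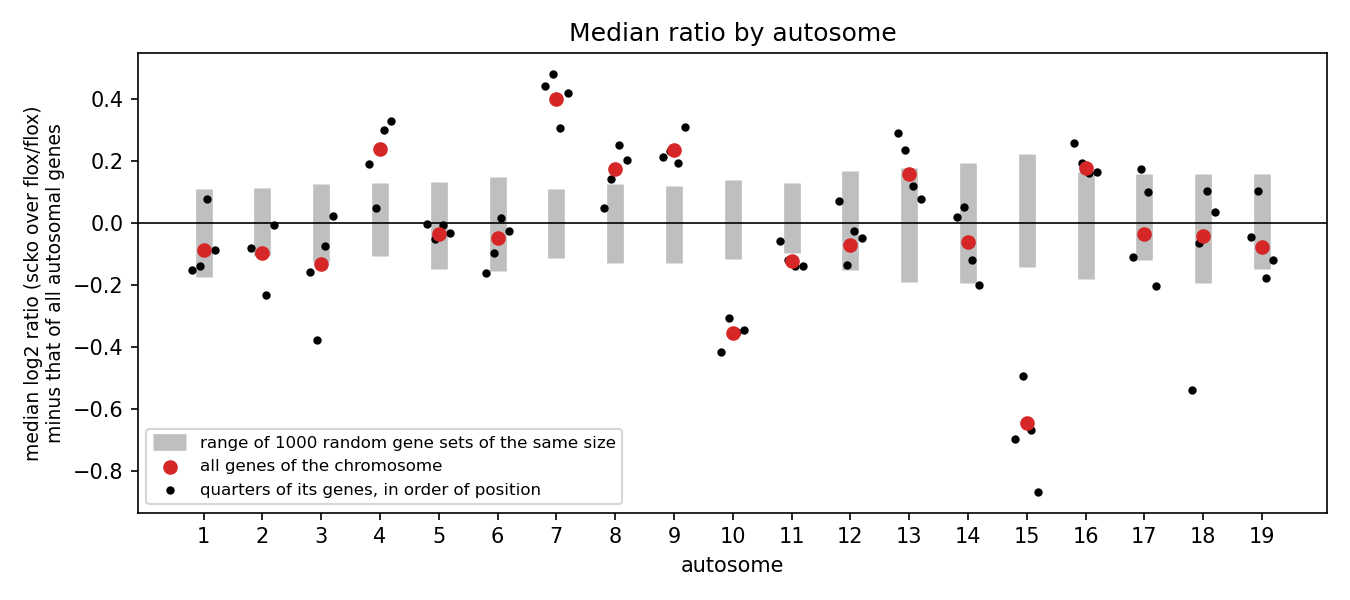
Median log2 ratio (Cipc scko over Cipc flox/flox) of each autosome minus that of all autosomal genes (red), of 4 equal groups of its genes in order of position (black), and the range of 1000 random gene sets of the same size (grey). Chromosome 15 lies lowest at -0.64 and chromosome 7 highest at 0.40.

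Across the transcriptome, 2732 of 12874 genes were at least 2-fold higher in the Cipc scko library and 2053 at least 2-fold lower, with a counting interval that excluded equality. Together these were 37.2% of the genes past the filter. Of them, 1037 were at least 10-fold higher and 481 at least 10-fold lower. Across genes, which are not independent replicates, log2(CPM + 0.5) of the libraries correlated with a Pearson r of 0.735 and a Spearman rho of 0.792. How much of this lies within the variation between animals cannot be measured here. In simulated libraries whose unchanged genes varied between animals with an assumed coefficient of variation of 0.4, the same rule called 3012 of 12498 unchanged genes.

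Genes were ranked by the interval limit nearest to equality. Among the 12 highest in Cipc scko, slow myosin Myh7 had 27995 counts in Cipc scko and 0 in Cipc flox/flox (at least 9838-fold), and the interferon-inducible GTPase Iigp1 had 18498 and 0 (at least 6501-fold). Cardiac actin Actc1 stood at 2113 and 0.177 CPM, and the fetal growth factor Igf2 at 4316 and 0.591 CPM. The others were H2-Q7, H2-Q6, Tgtp1, Tgtp2, Actn2, Psmb9, Rbm24 and Igtp. Tgtp1 and Tgtp2 are near-identical copies of each other, so their separate values are uncertain. The genes lowest in Cipc scko were Dynap, Pcdhga11, Blnk, Gsta2, Aqp5, Nefl, Igsf11, Add2, Nptx1, Nefm, Prl2c3 and Gchfr. Dynap had 0 counts against 4259 (at least 1347-fold lower) and the neurofilament gene Nefl 0 against 1820 (at least 575-fold lower). The water channel Aqp5 had 2 counts against 3655, a log2 ratio of -10.45 (-13.81 to -8.91). Gsta2 and Prl2c3 have near-identical copies and are likewise uncertain.

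**Figure D2:**
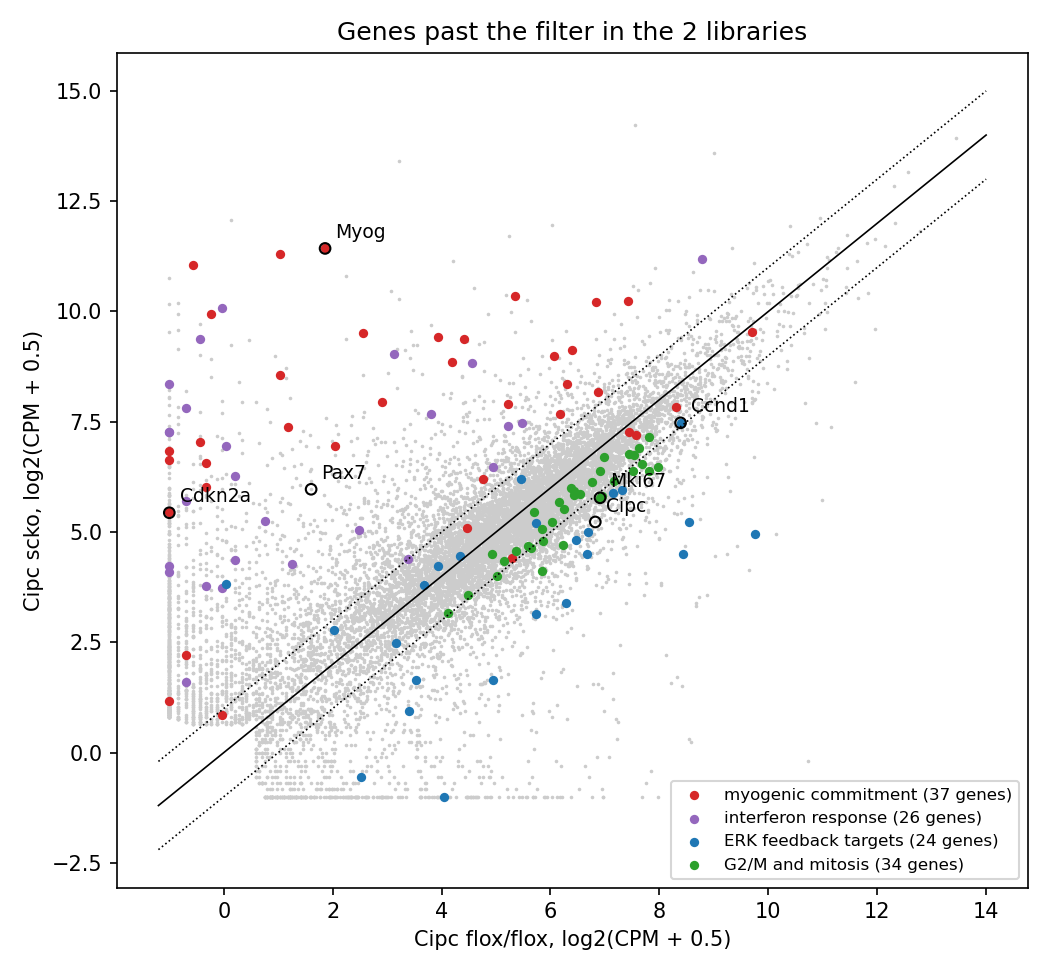
Expression of the genes past the filter in Cipc flox/flox (x axis) and Cipc scko (y axis), both as log2(CPM + 0.5), with members of 4 gene lists coloured, equality as a solid line and 2-fold differences as dotted lines. Myogenic commitment and interferon response genes lie mostly above the lines, while ERK feedback targets and G2/M genes lie mostly below equality.

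Muscle differentiation genes were far higher in Cipc scko. Of 37 myogenic commitment genes past the filter, 31 were higher and 0 lower, with a median log2 ratio of 5.01 (4.80 with genes at 0 counts set to their bound), the 100th percentile of 10000 random lists matched on expression. Myogenin (Myog), which drives terminal differentiation, stood at 2758 CPM in Cipc scko and 3.13 CPM in Cipc flox/flox, a log2 ratio of 9.77 (9.40 to 10.20). The myogenic regulator Myod1 stood at 1192 and 113 CPM (3.40, 3.33 to 3.47). The caveolin gene Cav3 had 1826 and 0 counts. Dok7 and Chrnd, genes of the neuromuscular junction, had lower values in Cipc scko (log2 -0.88 and -0.47) that did not reach 2-fold. Of 19 mature myofibre genes, 18 were higher and 0 lower (median 7.28, or 6.96 at the bound). Myoglobin (Mb) stood at 292.9 and 0.118 CPM, and Eno3 at 818 and 694 CPM, which was not a 2-fold difference.

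Genes of quiescent satellite cells went both ways, with 16 of 33 higher, 6 lower and a median log2 ratio of 0.99 (100th percentile). Pax7, the transcription factor that marks satellite cells, stood at 62.2 CPM in Cipc scko and 2.54 CPM in Cipc flox/flox (4.60, 4.17 to 5.09). Myf5 was close to equal at 66.2 and 61.6 CPM (0.10, -0.02 to 0.23), and its sign changed when libraries were scaled by totals. Fgfr4 had 4780 and 0 counts, while Cd34 had 3 counts in Cipc scko and 427 in Cipc flox/flox (-6.86, -9.36 to -5.52).

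**Figure D3:**
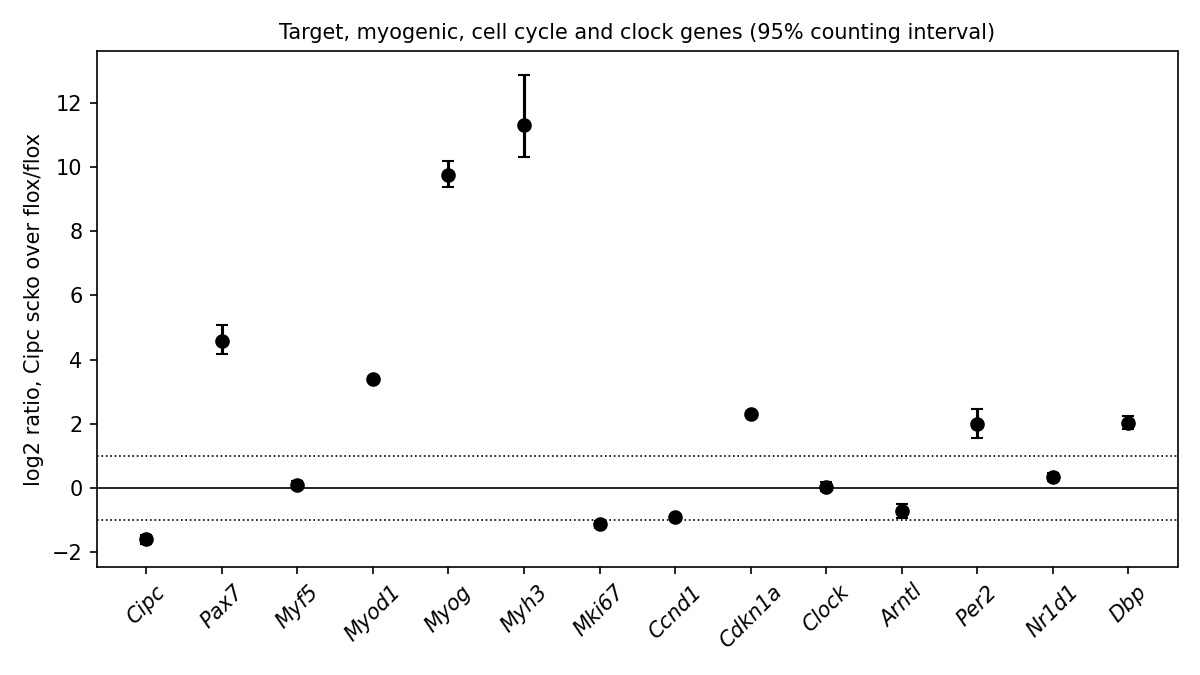
Log2 ratio of Cipc scko over Cipc flox/flox for Cipc, the 12 myogenic, cell cycle and clock genes fixed beforehand and Myh3, which was chosen after its value was seen, with 95% counting intervals and dotted lines at 2-fold. Cipc lies at -1.61, Myog at 9.77, Pax7 at 4.60 and Clock at 0.03.

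Proliferation genes were lower in Cipc scko. Of 33 DNA replication and G1/S genes, 17 were lower and 1, Ccne1, was higher (median log2 -1.01), and of 34 G2/M genes 12 were lower and 0 higher (median -0.80). Both medians lay below all 10000 random lists. The proliferation marker Mki67 stood at 54.3 and 119.8 CPM (-1.14, -1.26 to -1.02). The mitotic kinase Bub1 differed by -1.75 and the replication factor E2f2 by -2.04. Of 15 cell cycle inhibitors 7 were higher and 0 lower (median 0.57, percentile 98.7), a list that did not stand apart from unmatched random lists. Cdkn1a, which encodes p21, stood at 1912 and 391 CPM (2.29, 2.25 to 2.33), beside Cdkn2a and Cdkn2b at 0 in Cipc flox/flox. Of 8 G1 cyclins and kinases, Cdk4 was lower (-1.06) and Ccnd3 higher (1.88). Ccnd1, at 177.5 and 334.6 CPM, did not reach 2-fold (-0.91, -0.98 to -0.85). The median of that list was -0.04, turned positive with upper quartile scaling, and did not stand apart.

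Growth signalling genes split by pathway. Of 24 genes that respond to ERK signalling, 15 were lower in Cipc scko and 1 higher (median log2 -1.68, below all random lists). The membrane protein gene Emp1 stood at 30.5 and 861.9 CPM (-4.82, -4.96 to -4.69), and Epha4 had 0 and 271 counts. Spry1, an inhibitor of receptor tyrosine kinase signalling, went the other way (4.61, 3.74 to 5.84). Of 25 FoxO and atrophy genes 13 were higher and 3 lower (median 1.25, 100th percentile). The atrophy ubiquitin ligase Trim63 was 14.3-fold higher. Of 25 growth factor and IGF-AKT genes 6 were higher and 2 lower (median 0.33, percentile 96.2), with Igf2 at the top and the insulin receptor substrate Irs1 lowest (-3.34, -3.54 to -3.15).

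Since CIPC is a clock protein, clock genes were set out separately. Of 15 repressors and output genes, 5 were higher and 1 lower in Cipc scko (median log2 0.58, percentile 98.6). The clock output factor Dbp stood at 67.9 and 16.6 CPM (2.03, 1.84 to 2.23), Per2 had 209 and 55 counts (1.99, 1.57 to 2.46), and the deubiquitinase Usp2 stood at 57.0 and 3.07 CPM. The cell cycle kinase Wee1 was lower (-1.62). The list no longer stood apart without the filter on low counts or with unmatched random lists. Of 6 genes in the list fixed as activators, 3 were higher and 0 lower (median 1.11, percentile 91.4). It stood apart only among members of at least 5 CPM or with that filter. Its highest members were Rora (3.39) and Nfil3 (2.51). The list name does not hold for every member, since Nfil3 encodes a repressor. Clock was nearly equal at 52.6 and 51.5 CPM (0.03, -0.11 to 0.17), with a sign that changed under scaling by totals. Arntl, which encodes BMAL1, differed by -0.72 (-0.93 to -0.51) and Nr1d1 by 0.34 (0.21 to 0.46), neither reaching 2-fold. The times of day at which the cells were taken are not given in the sources used here.

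Interferon-response genes were higher in Cipc scko without exception. All 26 members past the filter were higher, with a median log2 ratio of 5.15 (100th percentile). The immunoproteasome subunit Psmb9 had 5222 and 0 counts (at least 1835-fold), and the chemokine Cxcl10 2477 and 0 counts (at least 870-fold). Ifit2 had the smallest difference among the members named by rule, at 20.4 and 9.93 CPM (1.04, 0.76 to 1.31). Of 14 inflammatory cytokine genes, 7 were lower and 3 higher (median -1.05, percentile 0.32), but the direction turned with summed counts (0.78). Ccl7 stood at 13.2 and 71.6 CPM and Csf1 at 515.6 and 118 CPM.

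Matrix, Notch and TGF-beta genes were mostly higher in Cipc scko. Of 33 extracellular matrix genes 20 were higher and 5 lower (median log2 1.36, 100th percentile). Collagen VI gene Col6a2 stood at 605 and 10.6 CPM and collagen I gene Col1a2 at 17.2 and 803 CPM. Of 16 Notch pathway genes 9 were higher and 2 lower (median 1.38), among them the ligand Dll1, 27.0-fold higher, and the glycosyltransferase Lfng, 4.53-fold lower. Of 20 TGF-beta and BMP targets 12 were higher and 1 lower (median 1.28). Follistatin (Fst) stood at 51.9 and 0.354 CPM, and Ltbp2 was 4.47-fold lower. Of 16 Wnt genes 8 were higher and 5 lower (median 0.65, percentile 86.8), with Wnt5a at 493 and 0 counts and Tcf7 4.29-fold lower. The Wnt list stood apart without the filter on low counts and with the stricter one. Among 30 immediate early genes 10 were higher and 6 lower (median 0.42, percentile 98.9), with Ccn2 17.9-fold higher and Klf4 4.93-fold lower. That list did not stand apart from unmatched random lists.

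**Figure D4:**
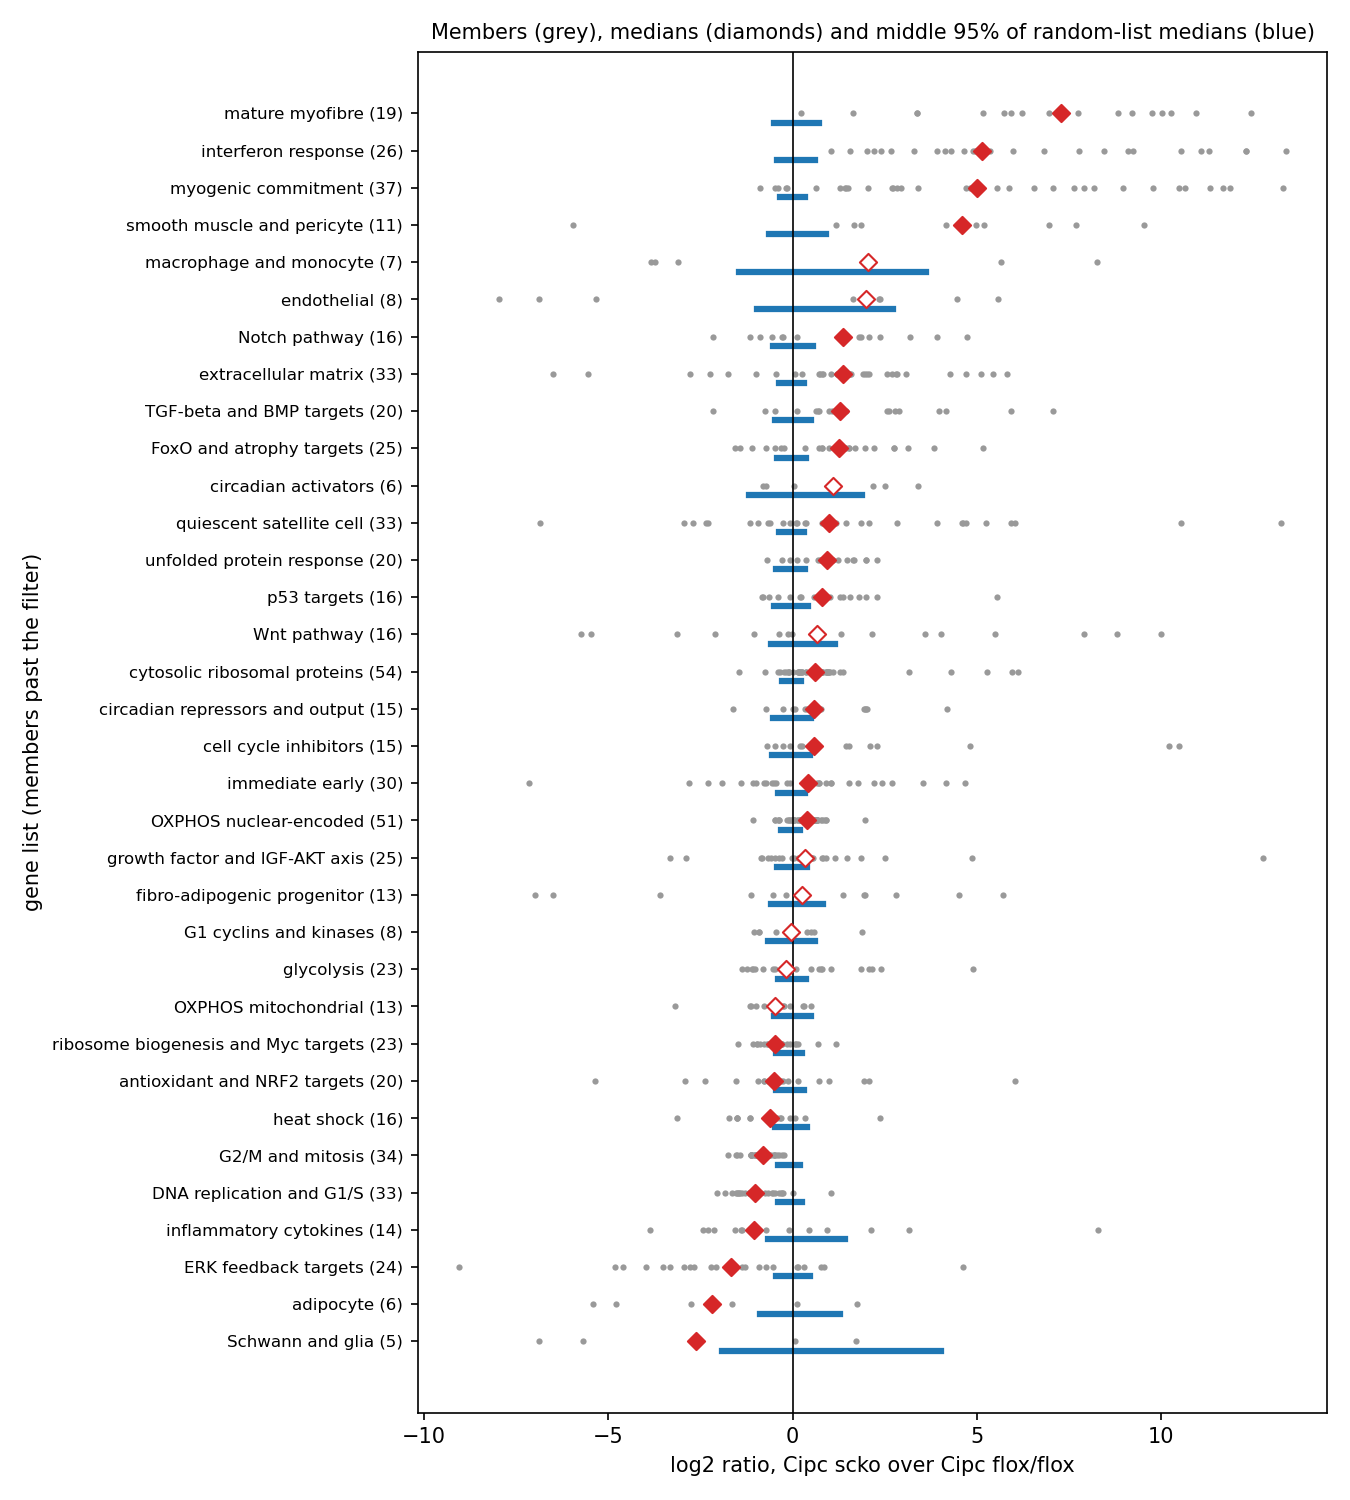
Log2 ratio (Cipc scko over Cipc flox/flox) of the members of 34 gene lists (grey points), their medians (diamonds, filled where the list stood apart from random lists) and the middle 95% of the medians of 10000 matched random lists (blue bars). Medians run from -2.62 for Schwann and glia to 7.28 for mature myofibre genes.

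Metabolic and stress lists had medians of both signs. Of 51 nuclear OXPHOS genes 1 was higher and 1 lower (median log2 0.38, percentile 99.95). Of 13 mitochondrially encoded genes 4 were lower (median -0.47, percentile 3.66). Among them mt-Atp6, which has a near-identical copy, stood at 337 and 3079 CPM, and the summed counts of that pair differed by -2.47 in log2. Of 23 glycolysis genes 6 were higher and 5 lower (median -0.19, percentile 23.4), and the median was 0.10 without genes that have near-identical copies. Gapdh stood at 640.0 and 21.5 CPM; copies outside the count table were not examined. Of 54 ribosomal protein genes 10 were higher and 1 lower (median 0.61, 100th percentile). Rps2 stood at 1472 and 23.8 CPM, but its pseudogene Rps2-ps10 at 0.374 and 1692 CPM, and their summed counts differed by only -0.22. Of 23 ribosome biogenesis genes 2 were lower and 1 higher (median -0.47, percentile 1.70). Of 20 unfolded protein response genes 8 were higher and 0 lower (median 0.94), and of 16 p53 targets 8 were higher and 0 lower (median 0.80). The ER stress gene Herpud1 was 4.85-fold higher. Of 20 NRF2 targets 4 were lower and 3 higher (median -0.50, percentile 1.31), with Gsta4 41.0-fold lower and Gpx3 65.6-fold higher. Of 16 heat shock genes 7 were lower and 1 higher (median -0.61, percentile 0.59), a list that no longer stood apart without genes that have near-identical copies.

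Markers of other cell types differed too. Of 11 smooth muscle and pericyte genes 10 were higher in Cipc scko and 1 lower (median log2 4.60, 100th percentile), although this list shares Des and Notch3 with the satellite cell list. Mcam stood at 151.5 and 0.709 CPM and Cspg4 at 0.436 and 29.0 CPM. Of 6 adipocyte genes 4 were lower and 1 higher (median -2.20), Pparg at 0.810 and 23.2 CPM. Of 5 Schwann cell genes 3 were lower and 1 higher (median -2.62, percentile 1.33), a call that ended under upper quartile scaling, FPKM and both other filters. The sign turned with the stricter filter (0.06) and with summed counts (0.82). Of 8 endothelial genes 5 were higher and 3 lower (percentile 93.6), of 7 macrophage genes 4 and 3 (percentile 89.7), and of 13 fibro-adipogenic genes 6 and 4 (percentile 71.5). Macrophage markers Cd68 and Cd14 stood at 1.87 and 1.43 CPM in Cipc scko and 25.1 and 21.0 CPM in Cipc flox/flox, while Cd74, the class II invariant chain, stood at 245.6 and 0.768 CPM. Neutrophil, lymphocyte, tenocyte and erythroid lists had 3, 2, 3 and 2 members past the filter, too few for a median. In all, 25 of 34 lists stood apart, 16 above and 9 below the random lists. For lists of independent genes 5% would do so by the definition used. Genes of a list can vary together and some lists share genes, so the share expected without an effect of genotype is unknown.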

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

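The filters without near-identical copies, without X and Y genes and with protein-coding genes only were chosen after seeing the data. Cipc stayed lower under all 9 alternatives run on it, from -1.74 with totals to -1.49 with FPKM and a pseudocount of 1. Among these, no filter and the filter of CPM 5 could not change the ratio of a gene. The counts depended on the size rule. A fold limit of 4 left 1608 genes higher and 860 lower, and a limit of 1.5 gave 3318 lower, because the limit itself sets how many pass. FPKM with a pseudocount of 1 gave 1479 higher (2369 with a pseudocount of 0.1), both on the same scaling, against 2491 with scaling by totals, so most of the drop goes with the pseudocount. An assumed coefficient of variation of 0.4 gave 1078 lower through its wider intervals. The other alternatives stayed within 1.5 times. Without X and Y genes 2650 were higher and 1962 lower. Scaling by totals moved the median of all genes by -0.14, so that 50.8% of calls were higher instead of 57.1%. Among the alternative list medians 11 had another sign, 7 of them in lists that did not stand apart (G1 cyclins and kinases, endothelial, macrophage, glycolysis) and 4 in lists that did. The Schwann and glia median became 0.0559 with members of at least 5 CPM and 0.0559 with the stricter filter, which keep fewer members, and 0.82 with summed counts. The inflammatory cytokine median became 0.78 with summed counts, which the most counted members decide. Between 24 and 26 lists stood apart under 12 alternatives, against 25, and 22 of the 25 did so with unmatched random lists. Lists that stood apart only under an alternative were Wnt and circadian activators (other filters), growth factor and IGF-AKT (no filter), and endothelial and macrophage (unmatched random lists). None of the 1494 alternative values of named genes reversed a ratio whose interval excluded equality. Those under the other filters are included in that number, although they could not differ. Depth limits genes with few counts in both libraries, and those with under 20 counts over both did not enter the main comparison.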

Other observations

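Of the tests below, those on multi-mapping reads and on whole chromosomes were fixed before their results were seen, and the others were chosen only after. Some genes outside the fixed lists were looked up after the lists were seen. The MHC class I genes H2-K1 and H2-D1 had 54129 and 63709 counts, against 630 and 1101 in Cipc flox/flox. The class II genes H2-Ab1, H2-Eb1 and H2-Aa had 7729, 5837 and 3364 counts, against 6, 6 and 4. Ciita, the master regulator of class II genes, had 599 counts against 0. The imprinted RNA H19 stood at 19054 and 186 CPM, beside Igf2 at 4316 and 0.591 CPM.

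Xist, Y-linked genes, Cdkn2a and Cdkn2b and chromosome medians differed between the libraries. A copy number change of whole chromosomes in 1 source was one hypothesis. Its bound, set beforehand, was at least 1 autosome over 0.2 away and outside its random range. The bound was met by 5 of 19 autosomes, with chromosome 15 farthest at -0.644. Chromosome 15 deviated by -0.67 once trends with GC content were taken off, which argues against GC bias. Copy number itself was not measured, so other causes of these medians are not excluded. Different treatment of multi-mapping reads stays open: 63.2% of 117 gene and pseudogene pairs moved the same way (53.8% to 72.0%), under the 75% set beforehand as the bound for it but not clearly under the 65% set as the bound against it. In 69.2% of the pairs the gene's share of the pair's counts moved by at most 5 points, so most moves were small. Strain variants stay open: 1 pair (Rps2 and Rps2-ps10) met the limits of at least 4-fold in opposite directions with a sum within 2-fold, random pairings gave up to 2, and other pairs shifted outside those limits, such as Rps18 with 96.6% of its pair's counts in Cipc scko and 8.65% in Cipc flox/flox. A swap of the labels cannot be told apart from the stated labels, since Cipc was lower at a ratio that 8.68% of genes reached. Autosome medians of log2(CPM + 0.5) ran from 4.995 to 5.438 in Cipc scko and from 4.718 to 6.049 in Cipc flox/flox. The medians were thus more uneven in Cipc flox/flox, where chromosome 15 stood highest. Without a reference profile, the values do not settle which library changed or what comes from sex rather than genotype. Nor do they settle whether both hold primary cells of the same kind or 1 passed through culture.

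Higher interferon-response and MHC genes in Cipc scko may come from leukocytes in the preparation. In Cipc scko the median CPM of 5 class II genes was 673 times that of 17 macrophage-list genes without Cd74. Those macrophage-list genes reached at most 2.30 CPM, which argues against macrophages and monocytes as the source. Other leukocytes were not tested in this way, and only 2 lymphocyte genes were past the filter. Type I against type II interferon could not be decided, because the genes were sorted into these kinds after their values were seen: 7 type II genes of the fixed list exceeded 11 type I genes by 5.21 in median log2 ratio, but the type I genes were themselves higher, with a median of 5.34. An effect of genotype stays open, which 1 library per group cannot test.

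Higher muscle differentiation genes in Cipc scko might reflect fragments of mature myofibres. The adult fast myosins Myh1, Myh2 and Myh4 gave 544 of 45980 sarcomeric myosin heavy chain counts, or 1.18%. This lay under a bound of 5%, but the bound and its narrowing to fast fibres were written after the values were seen. The share argues only against fast fibres as the main source of these myosin counts. Fragments of slow fibres stay open as a source of the Myh7 counts, since Myh7, the myosin of slow fibres, gave 60.9%. The developmental myosins Myh3 and Myh8 gave 37.8%. That share argues against mature slow fibres as the only source of myosin counts in the Cipc scko library. A later stage of differentiation at harvest, apart from genotype, cannot be told apart from an effect of genotype, because both are confounded with the single library of each group; the myogenic commitment median was 5.01.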
